A study of Mus musculus with 18 samples.

How the data were processed

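RNA was extracted with a Bio-Rad Aurum column kit from AML12 cells that had been seeded at 350000 cells per well in complete DMEM with 10% fetal bovine serum, left overnight and treated for 24 h, per the labels. Labelled RNA was hybridised in 1 colour (biotin) to an Illumina mouse BeadChip, a slide with 6 arrays of bead-bound probes. The 18 arrays fell into 4 groups by the treatment in the labels, with PBS (n = 5), 1 mM (n = 4), 2 mM (n = 5) and 5 mM octanoate (n = 4). The BeadChip of each array was read from the column names of the deposited signals.

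Kinds of values in use were as follows. The authors deposited the mean bead intensity of each of 45281 probes on each array, without background subtraction or normalization between arrays, per the file headers. Beside each intensity, per the file headers, they deposited a detection p-value, which the values show to move in steps of 0.00107 and which sets a probe against the array's negative control beads. The authors also deposited a table of processed log2 values of the same arrays. The submitters' processing notes name lumi, with its version not given in the sources used here. The normalization and transformation behind that table are likewise not given. Its scale was found by comparison: over bright probes, deviations from the mean on an array correlated at 0.978 to 0.998 with log2 of the same array's signal, with slopes of 0.89 to 0.96, so values were on a log2-like scale, not centred per gene, and ran in the same direction. Array medians of that table ran from 7.352 to 7.357. Whether a variance-stabilizing transform shaped the low end of that scale stays unknown. The table served only as an alternative.

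Signals were normalized with neqc of limma 3.58.1 in R 4.3.3 (statmod 1.5.0). This step infers the negative controls from the detection p-values, corrects the background with a normal and exponential model, adds an offset of 16, applies quantile normalization and takes log2. Quantile normalization gives all arrays 1 distribution, so a shift of most transcripts in 1 direction would be removed, and fold changes of dim probes are understated by the offset. Probes detected at p under 0.05 on at least 4 arrays were kept, 20536 of 45281 (45.4%), whichever group the arrays belonged to. Detected probes per array and the number of arrays per group set the precision. Of the probes in the files, 34885 had 1 gene symbol, 18 had several and 10378 are unnamed here. Symbols came from the platform annotation and were updated by Entrez ID through the RefSeq table of the mouse assembly GRCm38.p6, which matched 34807 of them, with the older symbol kept for 96 probes without a match. No coordinates are given, because the build behind the probes is not given in the sources used here. Among tested probes 17298 had 1 symbol and stood for 10605 genes. A gene was represented by its detected probe with the highest mean over all arrays. Of 4361 genes with several detected probes, 122 had probes called in opposite directions at 5 mM, 87 at 2 mM and 17 at 1 mM against PBS, 0 for 2 mM against 1 mM and 14 for 5 mM against 2 mM. Probe sequences were not used here, so cross-hybridization between near-identical genes was not examined.

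Group means were fitted with lmFit and eBayes of limma to all 18 arrays, so that the 4 groups shared 1 estimate of the spread (14 residual degrees of freedom, median residual SD 0.175). All tests were two-sided, and p-values were adjusted by the method of Benjamini and Hochberg over all tested probes, with calls at adjusted p under 0.05. Comparisons were each dose against PBS, 2 mM against 1 mM, 5 mM against 2 mM and a linear slope per mM. Errors of fold changes are standard errors of the fit, and errors of group levels are SD. A second fit had BeadChip as a fixed term and another had it as a random block. Where a probe was not detected on any array of a group, the fold is given as a bound. Design, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except 1 alternative, which left out 3 arrays and was added later. It is part of the ranges over alternatives.

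The rule for named genes took, for each dose against PBS, the 10 largest rises and the 10 largest falls among genes past adjusted p under 0.05 whose arrays did not overlap between the groups. For 2 mM against 1 mM and 5 mM against 2 mM it took 5 of each, and for the trend the 5 highest and 5 lowest slopes. Added were up to 4 members of each fixed list with the smallest adjusted p at 5 mM against PBS, and 7 genes whatever their result, of which 5 had a tested probe, Cpt1a had none and 1 is not analysed here. Probes without a single symbol were not named.

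Fixed lists numbered 31, with 652 genes, of which 474 were measured and 62 had no named probe. They covered mitochondrial and peroxisomal fatty acid oxidation, PPAR alpha targets, ketone bodies, medium-chain acyl-CoA enzymes, fatty acid and triglyceride synthesis, cholesterol, glycolysis, gluconeogenesis, the tricarboxylic acid cycle and oxidative phosphorylation. Others were histone acetyltransferases, deacetylases and sirtuins, acetyl-CoA supply, genes that deacetylase inhibitors induce, the integrated stress, unfolded protein, NRF2, heat shock and immediate early responses, cell cycle, p53 targets, interferon and inflammatory genes, autophagy and ribosomal proteins. The rest were markers of hepatocytes, cholangiocytes, mesenchymal cells, macrophages and endothelium. Lists with at least 5 measured genes (29) were tested with camera of limma, which compares a list with all other genes, at a preset correlation of 0.01 and again with the correlation estimated per list, on 1 probe per gene. Adjustment ran over the lists of a comparison. The roast approximation fry, which tests whether a list's genes move one way on balance, was also run.

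Overlaps between doses were set beside 100 simulated pairs of unchanged groups that shared the PBS arrays, beside the overlap of independent lists, and beside 20 splits of the PBS arrays. Other groupings of the same arrays were drawn 100 times per comparison. Alternatives covered background correction, normalization between arrays, the authors' table, the filter on dim probes, the threshold, a minimum change of 1.5-fold, array weights, a trended and robust prior, only the groups compared, BeadChip as a term or block or single BeadChips, the replicate number as a block, 1 probe per gene, the mean of a gene's probes, dose rank, and each array left out in turn.

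The procedure was tested on simulated data with 200 changed probes per comparison. The real comparisons called 4.79% to 53.5% of their probes, a larger share. The recovery and false calls given here need not hold for them. Of changed probes that were tested, the share recovered at 1.5-fold, 2-fold and 4-fold was 43.1%, 53.7% and 95.2% for 1 mM against PBS (23681 probes), 47.0%, 76.1% and 90.5% for 2 mM (23675) and 57.1%, 63.1% and 84.6% for 5 mM (23650). It was 59.1%, 67.2% and 81.5% for 2 mM against 1 mM (23834), 44.8%, 68.7% and 83.1% for 5 mM against 2 mM (23900) and 53.8%, 72.3% and 87.3% for the trend (23616). False calls made up 6.83%, 2.94%, 7.65%, 4.73%, 8.88% and 4.14% of the calls in the same order. A list shifted by 1.5-fold was found in all 6 simulations, and 1 of 29 other lists was called for 2 mM against 1 mM and 0 elsewhere.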

Results

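The series measured RNA in AML12 cells, an immortalized line of mouse hepatocytes, after 24 h with octanoate, a medium-chain fatty acid, or with phosphate-buffered saline (PBS) as the control. There were 18 arrays in 4 groups: PBS (n = 5), 1 mM octanoate (n = 4), 2 mM octanoate (n = 5) and 5 mM octanoate (n = 4). Each array was 1 section of an Illumina mouse BeadChip, a slide with bead-bound probes for 6 samples. The title of the series concerns lipid as a carbon source for the acetylation of histones. Of 45281 probes, 20536 (45.4%) were detected on at least 4 arrays and were tested, and they covered 10605 named genes. Detected probes per array ranged from 17446 to 19842, with means of 17918 ± 391 (SD, n = 5) for PBS, 18100 ± 317 (n = 4) at 1 mM, 18158 ± 179 (n = 5) at 2 mM and 19279 ± 551 (n = 4) at 5 mM. The number of arrays limits the precision, with a median standard error of 0.114 log2 units for 4 arrays against 5. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

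The arrays sat on 3 BeadChips of 6. BeadChip 1 held all PBS arrays and 1 mM replicate 1, BeadChip 2 held 1 mM replicates 2 to 4 and 2 mM replicates 1 to 3, and BeadChip 3 held 2 mM replicates 4 and 5 and all 5 mM arrays. Each comparison therefore carries a value from a fit with BeadChip as a term. For 1 mM against PBS, 2 mM against 1 mM and 5 mM against 2 mM this is also the estimate within the single BeadChip that held both groups. For 1 mM against PBS it rests on 1 array, 1 mM replicate 1, against 5. The BeadChip values of 2 mM and 5 mM against PBS chain through the same array, because no other links PBS to the rest, so they are not separate checks. With BeadChip as a random block, the correlation between arrays of a BeadChip was 0.035.

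Replicates correlated at 0.988 to 0.995 across probes, and no pair of arrays held identical values. The leading principal component held 57.7% of the variance and placed the groups in the order of dose, with means of −38.3 for PBS, −13.4 at 1 mM, 5.44 at 2 mM and 54.5 at 5 mM. The next component held 8.82% and set PBS (−13.7) and 5 mM (−11.5) apart from 1 mM (10.1) and 2 mM (14.8).

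**Figure D1:**
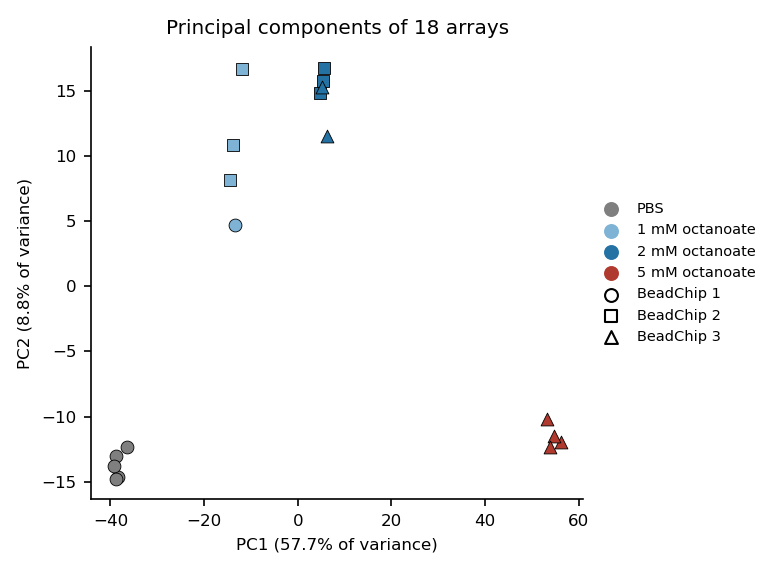
Each point is 1 array, placed by its scores on the leading principal components of the tested probes, in log2 units, with percent of variance on the axes and groups by colour. Group means on the horizontal axis run from −38.3 for PBS to 54.5 at 5 mM octanoate, and no groups mix.

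The comparison of 1 mM octanoate with PBS asked which transcripts changed at the lowest dose. Gsta4, a glutathione S-transferase that conjugates lipid aldehydes, rose by 1.92 ± 0.09 log2 units (SE; 3.77-fold, adjusted p = 1.8e-10). Ttr, the plasma carrier of thyroid hormone, rose 3.26-fold, Fcgrt, the receptor that recycles albumin and immunoglobulin G, 3.03-fold, and Aldh1a1, a retinaldehyde dehydrogenase, 2.78-fold. Flrt1 (2.84-fold), Apoc4 (1.49 log2 units), Synpo (1.49), Gstt1 (1.47), the fatty acid hydroxylase Cyp4a12a (1.47) and Apoe (1.44) completed the 10 largest rises. The falls were smaller. The cytokine Il24 (−1.09 ± 0.19) and Dis3, a ribonuclease of the RNA exosome (−1.05), fell most, followed by S100a7a (−0.996). The enzymes of sterol synthesis Lss (−0.98 ± 0.12) and Mvk (−0.96 ± 0.13) were also among the largest falls, with Wnt7a (−0.95), Zfand2a (−0.93), Dscc1 (−0.92), Rcc2 (−0.90) and the chemokine Cxcl10 (−0.90). Genes could be named among the largest changes of a comparison only if all arrays of one group lay above all arrays of the other, so this separation is no added support. With BeadChip as a term, Gsta4 was at 1.97 and Mvk at −0.83, while the falls of Il24 (−0.56, adjusted p = 0.258) and Cxcl10 (−0.66, adjusted p = 0.0757) no longer passed. Over the alternatives of the analysis their adjusted p ranged from 9.23e-06 to 0.258 and from 3.08e-05 to 0.0757.

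Fixed gene lists moved at 1 mM as follows, with each list's median log2 fold change, its value with BeadChip as a term, and camera's adjusted p. Of 17 measured genes of cholesterol synthesis and uptake 0 rose and 12 fell, or 1 and 13 adjusted over the list alone (median −0.54, BeadChip value −0.57, adjusted p = 2.3e-09). The cell cycle list had 16 of 29 genes lower and 0 higher, or 20 and 0 adjusted over the list alone (−0.39, −0.41, adjusted p = 2.3e-09). Of 17 hepatocyte markers 9 rose and 0 fell, or 11 and 0 adjusted over the list alone (0.39, 0.38, adjusted p = 5.74e-06). The peroxisomal fatty acid oxidation list had 7 genes higher and 1 lower of 17, or 13 and 1 adjusted over the list alone (0.26, 0.32, adjusted p = 1.85e-05), among them Acaa1b, a peroxisomal thiolase (0.89). Targets of PPAR alpha, the fatty acid receptor of hepatocytes, had 6 of 15 higher and 0 lower, or 7 and 0 adjusted over the list alone (0.23, 0.20, adjusted p = 0.000264). The acyl-CoA thioesterase Acot1 (1.06) rose with them, whereas Pdk4 (0.21, adjusted p = 0.25) did not pass.

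At 1 mM 5 other lists also passed. Mitochondrial fatty acid oxidation had 6 of 20 genes higher (7 adjusted over the list alone) and 0 lower, with a median of 0.17 (BeadChip value 0.11, adjusted p = 0.00115, but 0.0925 with BeadChip as a term and 0.0532 with median scaling, in a range from 2.1e-05 to 0.0925 over the alternatives). Medium-chain acyl-CoA enzymes and thioesterases had 6 of 13 higher and 1 lower (8 and 1 adjusted over the list alone; median 0.20, BeadChip value 0.44, adjusted p = 0.000264). NRF2 targets, genes of the oxidant response, had 11 of 25 higher and 1 lower (13 and 1 adjusted over the list alone; 0.22, 0.19, adjusted p = 0.000259). The integrated stress response list, set by amino acid supply among other stimuli, had 12 of 26 lower and 0 higher (14 and 1 adjusted over the list alone; −0.21, −0.27, adjusted p = 4.19e-05). Histone acetyltransferases had 7 of 17 lower and 1 higher, with the same numbers adjusted over the list alone (−0.15, −0.18, adjusted p = 0.0139, but 0.078 with BeadChip as a term and 0.0915 without 3 arrays that stood apart, in a range from 0.00879 to 0.0915 over the alternatives). All 10 lists also passed with an estimated correlation, and the others did not pass in the main fit. Genes that deacetylase inhibitors induce had 4 of 13 higher and 0 lower (0.26, adjusted p = 0.0627), but passed without PBS replicate 2 (0.0343) and without 1 mM replicate 3 (0.0272), in a range from 0.0189 to 0.237 over the alternatives. Heat shock genes did not pass but did without 1 mM replicate 4 (adjusted p = 0.0475, median −0.06), in a range from 0.0242 to 0.156 over the alternatives. Interferon-stimulated genes did not pass either, with adjusted p from 0.0263 (mean of a gene's probes) to 0.215, and passed also with median scaling (0.037) and without the filter on dim probes (0.0465). The p53 targets passed only without the 3 arrays that stood apart (0.0455) and without the filter (0.0465), in a range up to 0.747. In all, 3619 of 20536 probes changed (17.6%; 1922 higher and 1697 lower), 76 rose and 6 fell by at least 2-fold. With BeadChip as a term 1295 probes changed, 1015 of them called in the same direction in both fits. With the PBS arrays split so that no array was shared, 87.4% of the probes called without 1 mM replicate 1 had the same direction in that array, against 49.6% for a PBS array in its place. Without 1 mM replicates 1 and 4 and 2 mM replicate 5, which stood apart from their groups on a principal component, 2084 probes were called (a choice made after seeing the data). Median scaling in place of quantile normalization called 498 higher and 2032 lower, with the median of all probes at −0.11 in place of −0.01, so the balance of rises and falls at 1 mM depends on the scaling.

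The comparison of 2 mM octanoate with PBS asked the same at the middle dose. Gsta4 was 7.57-fold higher (2.92 ± 0.09 log2 units, adjusted p = 2e-14), Ttr 6.56-fold, Fcgrt 4.94-fold and Aldh1a1 4.84-fold. Apoe (2.27) and Apoc4 (2.27) rose further than at 1 mM in their fold over PBS, and Ddc (2.21), which decarboxylates aromatic amino acids, Fbxo2 (2.19) and Ffar4 (2.18), a receptor for long-chain fatty acids, joined them. Keg1 was not above background on any PBS array and was at least 3.49-fold higher at 2 mM. Such a bound sets the mean of the brighter group against, on each array of the dim group, the higher of the dim probe and the lowest detected probe. Tcof1, a nucleolar factor of ribosomal RNA synthesis, fell by 1.49 ± 0.10, and Wnt7a (−1.39), Mvk (−1.39), Lss (−1.34), Pcolce2 (−1.32), Ifrd2 (−1.25), Zc3h18 (−1.25) and Armc6 (−1.21) followed. With BeadChip as a term Gsta4 was at 3.02 and Tcof1 at −1.49, while Il24 (−1.36, BeadChip value −0.69, adjusted p = 0.231) and Prrc2c (−1.33, BeadChip value −1.19, adjusted p = 0.107) no longer passed. Over the alternatives their adjusted p ranged from 3.49e-09 to 0.231 and from 2.41e-08 to 0.107.

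At 2 mM the cholesterol list had 13 of 17 genes lower and 1 higher, with the same numbers adjusted over the list alone (median −0.66, BeadChip value −0.77, adjusted p = 1.02e-07). The cell cycle list had 25 of 29 lower and 1 higher, or 26 and 1 adjusted over the list alone (−0.49, −0.47, adjusted p = 1.35e-08). The integrated stress response list had 18 of 26 lower and 1 higher, or 19 and 1 adjusted over the list alone (−0.39, −0.43, adjusted p = 3.52e-07), with the serine and folate enzymes Shmt2 (−1.03) and Mthfd2 (−0.78) among the falls. The peroxisomal list had 15 of 17 higher and 0 lower, or 15 and 1 adjusted over the list alone (0.35, 0.38, adjusted p = 1.18e-05), and PPAR alpha targets had 11 of 15 higher and 0 lower, or 11 and 1 adjusted over the list alone (0.42, 0.37, adjusted p = 9.96e-05). Medium-chain acyl-CoA enzymes had 9 of 13 higher and 1 lower, or 9 and 2 adjusted over the list alone (0.48, 0.69, adjusted p = 0.00105), and hepatocyte markers had 10 of 17 higher and 0 lower, with the same numbers adjusted over the list alone (0.41, 0.49, adjusted p = 5.65e-05). NRF2 targets had 12 of 25 higher and 3 lower, or 14 and 4 adjusted over the list alone (0.27, 0.11, adjusted p = 0.00147).

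The list of p53 targets passed at 2 mM, with 9 of 16 genes higher and 0 lower, or 10 and 0 adjusted over the list alone (median 0.27, BeadChip value 0.20, adjusted p = 0.00147, but 0.129 with BeadChip as a term, in a range from 0.000132 to 0.129 over the alternatives). Zmat3 (0.81) and Fas (0.78) were among the rises. Inflammatory cytokines and NF-kB targets had 12 of 21 lower and 2 higher, or 12 and 3 adjusted over the list alone (−0.27, −0.33, adjusted p = 0.00553), with the adhesion molecule Vcam1 at −0.68. Mitochondrial fatty acid oxidation had 10 of 20 higher and 0 lower, or 11 and 0 adjusted over the list alone (0.23, 0.15, adjusted p = 0.00147, but 0.121 with BeadChip as a term, in a range from 1.68e-05 to 0.121). Glycolysis had 7 of 16 lower and 1 higher, with the same numbers adjusted over the list alone (−0.16, −0.26, adjusted p = 0.0367; adjusted p = 0.102 with an estimated correlation). Without PBS replicate 5 the adjusted p of glycolysis was 0.0657, in a range from 0.00912 to 0.102 over the alternatives. Histone acetyltransferases had 7 of 17 lower and 2 higher, or 8 and 2 adjusted over the list alone (−0.18, −0.03, adjusted p = 0.038; adjusted p = 0.0538 with an estimated correlation). Several settings ended the call of the acetyltransferases, among them BeadChip as a term (0.158) and leaving out PBS replicate 5 (0.0568), in a range from 0.0255 to 0.158. In all 7615 probes changed (37.1%; 3743 higher and 3872 lower), with 294 higher and 66 lower by at least 2-fold, and 2134 probes changed with BeadChip as a term, of which 1863 were called in the same direction in both fits. Median scaling called 2229 higher and 3053 lower, so the balance at 2 mM depends on the scaling too.

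The comparison of 5 mM octanoate with PBS asked which transcripts changed at the highest dose. Ttr rose by 4.22 ± 0.10 log2 units (18.7-fold, adjusted p = 4.7e-17; BeadChip value 3.88), Rnase4 by 4.19 ± 0.12 and Gsta4 by 4.19 ± 0.09, both 18.2-fold. Fbxo2 (3.77), Aldh1a1 (3.55, 11.7-fold), the peptidase Xpnpep2 (3.42), Cyp2c67 (3.34) and Sprr2g (3.33) were next. Aldh1a7 and Frmd5, which were not above background on any PBS array, were at least 9.99-fold and 9.78-fold higher. Bounds and folds are those of a gene's brightest probe. Other probes of the same genes gave less, at 1.09 for Rnase4, 0.34 for Frmd5 and 0.14 for Xpnpep2, the last not called. Of 68 named genes with several tested probes, 14 had a probe that was not called at 5 mM beside one that was. Of the 10 largest falls 5 were in histone H2A genes. H2ac11 (−3.72 ± 0.11), H2ac21 (−3.70), H2ac15 (−3.43), H2ac22 (−3.21) and H2ac12 (−3.21) were these. Cdc20, the activator of the anaphase-promoting complex, was at −3.54 ± 0.10 (adjusted p = 3.4e-16; BeadChip value −3.17). Birc5, or survivin (−3.21), Cdca8, or borealin (−3.15), the spindle checkpoint kinase Bub1b (−3.12) and D17H6S56E-5 (−3.12, with another probe at −0.79) followed. Probes of the same gene also differed by at least 1 log2 unit at 5 mM for Flrt1 (1.53 to 2.64), Lss (−1.42 to −0.18), Cxcl2 (−1.66 to −0.62), Aldh1l2 (0.50 to 1.85), Bdh1 (0.60 to 1.63), Fas (0.14 to 1.42), Usp18 (0.61 to 2.55), Vcam1 (−1.73 to −0.39) and Fn1 (−0.13 to 1.11).

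The cell cycle list had 28 of 29 measured genes lower at 5 mM and 1 higher, with the same numbers adjusted over the list alone (median −2.36, BeadChip value −2.22 with 26 lower and 0 higher, adjusted p = 1.94e-19). Plk1, a mitotic kinase (−3.01 ± 0.09), and Mcm5, a subunit of the replicative helicase (−2.76 ± 0.08), were among the falls. Of 16 p53 targets 15 rose and 0 fell, with the same numbers adjusted over the list alone (0.79, BeadChip value 0.72, adjusted p = 1.5e-05). Fas rose by 1.38, Trp53inp1 by 1.33, Zmat3 by 1.26 and Ccng1 by 1.06, and Cdkn1a, the inhibitor of cyclin-dependent kinases, rose by 0.92 ± 0.08 (1.89-fold; BeadChip value 0.71). Inflammatory cytokines and NF-kB targets had 17 of 21 genes lower and 1 higher, with the same numbers adjusted over the list alone (−1.26, BeadChip value −1.36, adjusted p = 2.85e-09). The acute-phase genes Saa3 (−3.06 ± 0.13) and Lcn2 (−2.31 ± 0.11), the adhesion molecule Vcam1 (−1.73) and the chemokine Cxcl1 (−1.46) fell most clearly.

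PPAR alpha targets had 11 of 15 higher and 0 lower at 5 mM, with the same numbers adjusted over the list alone (median 0.90, BeadChip value 0.99, adjusted p = 4.07e-05). Pdk4, the kinase that shuts off pyruvate dehydrogenase, rose by 3.24 ± 0.12 (9.44-fold), Acot1 by 2.00 ± 0.07 and Angptl4, an inhibitor of lipoprotein lipase, by 1.97 ± 0.08. The peroxisomal list had 14 of 17 higher and 0 lower, or 15 and 0 adjusted over the list alone (0.73, 0.70, adjusted p = 2.81e-05), with Acaa1b at 1.85, Acox2 at 1.62 and Ech1 at 0.95. Acot4, not above background on any PBS array, was at least 4.25-fold higher. Mitochondrial fatty acid oxidation had 13 of 20 higher and 1 lower, with the same numbers adjusted over the list alone (0.39, 0.23, adjusted p = 0.00431, but 0.0738 with BeadChip as a term, in a range from 6.52e-05 to 0.0738 over the alternatives). The carnitine carrier Slc25a20 rose by 1.62, the thiolase Acaa2 by 1.51, Etfdh by 1.24 and Etfb by 1.02, and Acadm, the medium-chain acyl-CoA dehydrogenase, by 0.90 ± 0.08. Cpt1a, which loads long-chain fatty acids onto carnitine, was detected on at most 1 array by its 2 probes and was not tested. Medium-chain acyl-CoA enzymes and thioesterases had 9 of 13 higher and 2 lower, with the same numbers adjusted over the list alone (0.87, 0.99, adjusted p = 0.00431). Acot6 was at 1.58 and Acot2 at 1.79, although another probe of Acot2 gave −0.49.

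Hepatocyte markers had 12 of 17 higher and 0 lower at 5 mM, with the same numbers adjusted over the list alone (median 1.07, BeadChip value 0.91, adjusted p = 0.000121). Apoe rose by 2.44 and the hepatocyte transcription factor Hnf4a by 1.07, and transferrin (Trf) was 2.82-fold higher. NRF2 targets had 12 of 25 higher and 3 lower, or 13 and 3 adjusted over the list alone (0.22, 0.16, adjusted p = 0.00431), with a mean of 0.71 above the median because a few genes rose far. Besides Gsta4, these included Ephx1, an epoxide hydrolase (2.43), Blvrb (2.34), Gstm2 (1.72) and Gstp1 (1.54). The cholesterol list had 12 of 17 lower and 1 higher, with the same numbers adjusted over the list alone (−0.69, −0.67, adjusted p = 0.000184). Mvk (−2.14), Cyp51 (−1.55), Fdps (−1.30) and Sqle (−1.02) fell. Histone acetyltransferases had 8 of 17 lower and 2 higher, or 9 and 2 adjusted over the list alone (−0.23, −0.19, adjusted p = 0.0284, but 0.085 with BeadChip as a term and 0.0525 with a stricter filter on dim probes, in a range from 0.0238 to 0.085 over the alternatives). Hat1, which acetylates newly made histone H4, fell by 1.75 ± 0.09. Kat5 (−0.83), Kat7 (−0.79) and Kat2a (−0.77) also fell, but Kat5 did not pass with BeadChip as a term (−0.51, adjusted p = 0.077, the highest over the alternatives, and 1.56e-10 the lowest). All 11 lists called at 5 mM also passed with an estimated correlation.

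The remaining lists did not pass as a whole at 5 mM. Acetyl-CoA supply outside mitochondria had 6 of 9 genes higher and 0 lower (median 0.42, adjusted p = 0.0658). It passed without PBS replicate 2 (0.0411) and without 5 mM replicate 3 (0.0438), in a range from 0.0184 to 0.234 over the alternatives. Acss2, which makes acetyl-CoA from acetate, rose by 1.66 ± 0.13, Idh1 by 1.04 and Slc25a1 by 0.42 (adjusted p from 4.08e-05 to 0.345 over the alternatives, the highest with BeadChip as a term, at 0.34), whereas Acly, which makes acetyl-CoA from citrate, was at −0.16 ± 0.09 and did not pass (adjusted p = 0.16). Histone deacetylases and sirtuins had 7 of 16 higher and 2 lower (0.21, adjusted p = 0.42), with Hdac11 at 1.39, Hdac8 at 0.99, Sirt1 at −0.65 and Hdac10 at −0.74 (adjusted p from 1.96e-06 to 0.0854, the highest with BeadChip as a term, at −0.77). Genes that deacetylase inhibitors induce had 8 of 13 higher and 5 lower (0.45, adjusted p = 0.277). Of these Glrx (0.93) and Txnip (0.92) rose and Gadd45b (−1.26) fell. Autophagy and lysosome genes had 11 of 21 higher and 1 lower (0.34, adjusted p = 0.0531, in a range from 0.00382 to 0.23), with Gabarapl1 and Atg9b both at 1.48, Wipi1 at 0.75 and Atp6v1h at 0.50. The list passed without PBS replicate 1 (0.0487) or 2 (0.0478) and without 5 mM replicate 2 (0.0475) or 3 (0.0438). Fatty acid and triglyceride synthesis had 13 of 22 higher and 2 lower (0.29, adjusted p = 0.127, in a range from 0.0275 to 0.323 over the alternatives). This list passed only without the filter on dim probes (0.0275). The desaturase Scd1 rose by 1.51, Dgat2 by 0.98, Acsl3 by 0.85 and Lpin1 by 0.89 (adjusted p from 3.8e-09 to 0.0665, the highest with BeadChip as a term, at 0.67). Ketone body metabolism had 3 of 6 higher and 2 lower (0.86, adjusted p = 0.343), with Slc16a6 at 2.21, Bdh2 at 1.88, Bdh1 at 1.63 and Aacs at −1.13.

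Glycolysis had 3 of 16 genes higher and 7 lower at 5 mM (median −0.11, adjusted p = 0.322), with Pfkm at 1.18, Pfkp at 0.91, Pfkl at −0.90 and the glucose carrier Slc2a1 at −0.93. Gluconeogenesis and fasting response had 4 of 7 higher and 1 lower (0.26, adjusted p = 0.535). The tricarboxylic acid cycle and pyruvate dehydrogenase list had 3 of 19 higher and 5 lower (−0.08, adjusted p = 0.554), and oxidative phosphorylation 10 of 34 higher and 9 lower (−0.03, adjusted p = 0.767), with Ndufa1 at 0.65 and Ndufs8 at −0.57. The integrated stress response list had 6 of 26 higher and 12 lower (−0.22, adjusted p = 0.143). Atf5 rose by 0.93, while Shmt2 (−1.37), Atf3 (−1.22) and Mthfd2 (−0.74) fell. The unfolded protein response list had 1 of 17 higher and 9 lower (−0.21, adjusted p = 0.176), with Hyou1 at −0.54 and Creld2 at −0.44 (adjusted p from 9.38e-05 to 0.0825, the highest with median scaling). Heat shock genes had 8 of 15 higher and 5 lower, with a median of 0.25, a mean of 0.04 and a median of −0.03 with BeadChip as a term (adjusted p = 0.842), and Hspa4 was at −0.92. Immediate early genes had 4 of 14 higher and 8 lower (−0.23, adjusted p = 0.518), with Ccn2 at 1.34, Dusp6 at 0.64 and Myc at −0.92. Interferon-stimulated genes had 8 of 14 higher and 2 lower (0.38, adjusted p = 0.127). For Usp18 and Oasl1 the brighter probe was not above background on any PBS array and was at least 4.70-fold and 1.81-fold higher, while their other probes rose by 0.61 and 0.67. Ifit3 rose by 0.99, and Cxcl10, not above background at 5 mM, was at least 2.15-fold lower. Ribosomal proteins had 4 of 18 higher and 4 lower (−0.05, adjusted p = 0.535), with Rpl14 at −0.99, Rplp0 at −0.60 and Rpl22 at 0.63.

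Markers of other liver cell types showed no common shift at 5 mM. Cholangiocyte and progenitor markers had 1 of 5 higher and 2 lower, with a median of 0.07 and a mean of −0.11 (adjusted p = 0.738). Krt7 was at −1.08 and Sox9 at 0.34, and neither passed with BeadChip as a term (−0.68 and 0.15, adjusted p = 0.087 and 0.61, the highest over the alternatives, with 7.65e-10 and 1.61e-05 the lowest). Cftr was at 0.36 (adjusted p = 0.06, in a range from 0.0233 to 0.247) and passed without PBS replicate 5 (0.0288) and without 5 mM replicate 1 (0.0418) or 4 (0.0317). Mesenchymal and stellate cell markers had 6 of 12 higher and 1 lower (0.24, adjusted p = 0.435), with Fn1 at 1.11, Sparc at 1.01, Col5a1 at 0.71 and Vim at −0.65, the last 2 of which did not pass with BeadChip as a term (0.45 and −0.32, adjusted p = 0.35 and 0.29, with 8.17e-07 and 5.15e-10 the lowest over the alternatives). The macrophage and leukocyte list had only 3 measured genes, of which Cd14 fell by 0.87, and C1qa (−0.21; adjusted p = 0.0324 without PBS replicate 4) and Csf1r (0.16) did not pass. Of 4 measured endothelial markers Kdr, not above background at 5 mM, was at least 1.10-fold lower and Eng was at −0.27, neither passing with BeadChip as a term (−0.41 and −0.21, adjusted p = 0.34 and 0.56, with 0.00109 and 0.00628 the lowest over the alternatives), and Tek (−0.19) and Clec4g (−0.14) did not pass. Eng did not pass without PBS replicate 1 (0.0521) or 2 (0.0594) or without 5 mM replicate 2 (0.0849) or 4 (0.0654). These 2 lists were too short to test. Of the lists that did not pass at 5 mM, counts adjusted over the list alone differed for fatty acid synthesis (13 higher, 3 lower), the tricarboxylic acid cycle (1 and 1), oxidative phosphorylation (11 and 11), the integrated stress response (6 and 13), heat shock (8 and 6), ribosomal proteins (3 and 4), cholangiocyte markers (2 and 2) and mesenchymal markers (6 and 3).

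**Figure D2:**
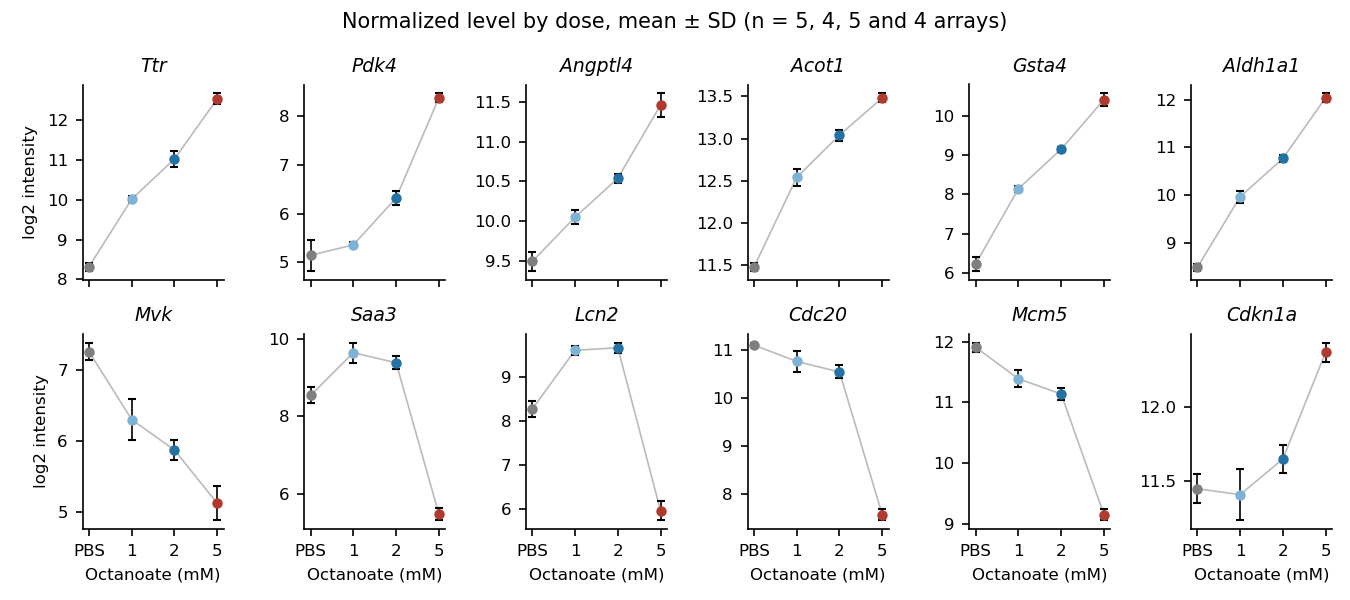
The vertical axis is the normalized log2 signal and the horizontal axis octanoate in mM, where each point is a group's mean and each bar its SD (n = 5, 4, 5 and 4 arrays), for 12 named genes. Ttr climbs at each dose to 4.22 log2 units above PBS, whereas Saa3 and Lcn2 lie above PBS at 1 mM and 2 mM and below it at 5 mM.

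In all 10986 of 20536 probes changed at 5 mM (53.5%; 5586 higher and 5400 lower), with 1101 higher and 938 lower by at least 2-fold. With BeadChip as a term 4965 changed, of which 4667 were called in the same direction in both fits and 1 in the opposite direction. Median scaling called 6191 higher and 3270 lower. Some further calls at 5 mM were lost with BeadChip as a term, which has a larger standard error, whether or not the change kept its size. Among the rises were Pcx (0.34, BeadChip value 0.05), Ppargc1a (0.33, BeadChip value 0.43), Suclg1 (0.47 and 0.35), Cox6b1 (0.52 and 0.28), Ndufa4 (0.45 and 0.41), Chordc1 (0.43 and 0.25) and Bag3 (0.40 and 0.37). Among the falls were Sik1 (−0.79, BeadChip value −0.85), Hspd1 (−0.46 and −0.53), Calr (−0.41 and −0.41), Hsp90b1 (−0.34 and −0.46), Rps15 (−0.31 and −0.24), Mdh2 (−0.30 and −0.28), Krt19 (−0.25 and −0.27), Idh3a (−0.20 and −0.05) and Idh3g (−0.19 and −0.45). With median scaling the calls of Calr (−0.29), Hsp90b1 (−0.33), Mdh2 (−0.20), Krt19 (−0.15), Idh3g (−0.16), Idh3a (−0.07, adjusted p = 0.748), Creld2 (−0.31) and Eng (−0.24, adjusted p = 0.158) were lost. Leaving out single arrays ended the calls of Pcx (adjusted p = 0.104 without PBS replicate 2, the highest of 7), Idh3g (0.0932 without 5 mM replicate 4, the highest of 5), Idh3a (0.0804 without 5 mM replicate 4, the highest of 4) and Ppargc1a (0.0585 without 5 mM replicate 3). Over all alternatives the adjusted p reached 0.935 for Pcx, 0.394 for Idh3g and 0.867 for Idh3a, from lows of 0.00408, 0.00164 and 0.00776.

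The comparison of 2 mM with 1 mM octanoate asked what the step between the lower doses changed. Aldh1a7 rose by 1.15, Ddc by 1.02, Keg1 by 1.01, Ttr by 1.01 and Gsta4 by 1.00. Zc3h18 (−0.87), the neutrophil chemokine Cxcl2 (−0.71) and Tcof1 (−0.65) fell, whereas Prrc2c (−0.89) and Gtf2a1 (−0.67) did not pass with BeadChip as a term (−0.91 and −0.68, adjusted p = 0.102 and 0.0749, in ranges from 0.00386 to 0.189 and from 0.00543 to 0.149). Prrc2c also did not pass without 1 mM replicate 1 (0.0649) or 2 (0.0819) or without 2 mM replicate 2 (0.0593). A fit of only the 6 arrays of BeadChip 2, which called 27 probes, no longer called Aldh1a7 (1.15, adjusted p = 0.137), Zc3h18 (−0.73, 0.0623), Cxcl2 (−0.76, 0.116) and Tcof1 (−0.62, 0.103), with each p the highest over the alternatives, from lows of 3.06e-06, 1.89e-07, 0.0015 and 4.53e-06. With median scaling Tcof1 was at −0.54 (adjusted p = 0.0619). Without 1 mM replicate 2, 650 probes were called, and 358 without the 3 arrays that stood apart on a principal component. In all 984 probes changed (4.79%; 639 higher and 345 lower), 373 with BeadChip as a term, 335 of them in both fits. Median scaling called 417 higher and 15 lower. Inflammatory genes had 4 of 21 lower and 0 higher, or 14 and 1 adjusted over the list alone (median −0.28, BeadChip value −0.30, adjusted p = 5.77e-08). The integrated stress response list had 3 of 26 lower and 0 higher, or 7 and 0 adjusted over the list alone (−0.19, −0.20, adjusted p = 5.71e-06), and glycolysis 4 of 16 lower and 1 higher, or 8 and 1 adjusted over the list alone (−0.16, −0.20, adjusted p = 0.000171). PPAR alpha targets had 4 of 15 higher and 0 lower, or 7 and 0 adjusted over the list alone (0.21, 0.19, adjusted p = 0.000293), and p53 targets 1 of 16 higher and 0 lower, or 7 and 0 adjusted over the list alone (0.19, 0.18, adjusted p = 0.000534). The cholesterol list (−0.15; adjusted p = 0.119 with an estimated correlation), the cell cycle list (−0.11; adjusted p = 0.244 with an estimated correlation) and mitochondrial fatty acid oxidation (0.09; adjusted p = 0.0756 with an estimated correlation) passed only with the preset correlation.

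The comparison of 5 mM with 2 mM octanoate asked what the highest dose added. Rnase4 rose by 2.60 ± 0.12, Aldh1l2, a mitochondrial folate enzyme, by 2.26, Ckmt1, mitochondrial creatine kinase, by 2.23, Frmd5 by 2.10 and Pdk4 by 2.06 ± 0.12 (4.17-fold). Saa3 (−3.90 ± 0.13, adjusted p = 7.3e-15; −4.00 within BeadChip 3), Lcn2 (−3.70 ± 0.11; −3.60 within BeadChip 3), Cdc20 (−2.98), Birc5 (−2.96) and Bub1b (−2.81) fell most. The cell cycle list had 27 of 29 lower and 1 higher, or 28 and 1 adjusted over the list alone (median −1.82, BeadChip value −1.72, adjusted p = 4.84e-30). Inflammatory genes had 15 of 21 lower and 0 higher (−0.90, −0.87, adjusted p = 2.5e-12), p53 targets 14 of 16 higher and 0 lower (0.49, 0.51, adjusted p = 2.94e-06) and PPAR alpha targets 9 of 15 higher and 0 lower (0.32, 0.30, adjusted p = 4.05e-05), all with the same numbers adjusted over the list alone. The peroxisomal list had 10 of 17 higher (11 adjusted over the list alone; 0.30, 0.35, adjusted p = 0.00132), hepatocyte markers 8 of 17 (9 adjusted over the list alone; 0.28, 0.26, adjusted p = 0.0068), NRF2 targets 11 of 25 (12 adjusted over the list alone; 0.27, 0.20, adjusted p = 0.0124) and autophagy 7 of 21 (9 adjusted over the list alone; 0.23, 0.21, adjusted p = 0.0189). Acetyl-CoA supply (5 of 9 higher; adjusted p = 0.0805 with an estimated correlation), fatty acid synthesis (9 of 22 higher; adjusted p = 0.0805 with an estimated correlation), medium-chain enzymes (8 of 13 higher; adjusted p = 0.0661 with an estimated correlation) and mitochondrial oxidation (11 of 20 higher; adjusted p = 0.07 with an estimated correlation) passed only with the preset correlation. The integrated stress response list turned, with 11 of 26 higher and 3 lower, or 13 and 3 adjusted over the list alone (0.21, BeadChip value 0.25, adjusted p = 0.0234; adjusted p = 0.0805 with an estimated correlation). Atf5 rose by 1.30 between these doses. Cholesterol genes did not move further as a list (−0.03, adjusted p = 0.44). In all 5873 probes changed (28.6%; 3167 higher and 2706 lower), 4359 with BeadChip as a term, 4015 of them in both fits. Median scaling called 4773 higher and 1043 lower, with the median of all probes at 0.16 in place of 0.01.

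The dose trend asked which transcripts followed dose over all 4 groups. Rnase4 rose by 0.85 ± 0.02 log2 units per mM, Ttr by 0.80 ± 0.06, Gsta4 by 0.78 ± 0.07, Aldh1a7 by 0.75 ± 0.04 and Frmd5 by 0.74 ± 0.03. The slopes of Aldh1a7 and Frmd5 include PBS arrays on which neither was above background, so their size is uncertain. H2ac11 (−0.75 per mM), H2ac21 (−0.74), Cdc20 (−0.72), Saa3 (−0.70 ± 0.11) and H2ac15 (−0.69) fell, although Saa3 was above PBS at 1 mM (1.10) and 2 mM (0.84). In all 10367 probes had a slope (50.5%; 5347 up and 5020 down), 4675 with BeadChip as a term and 4425 in both fits. Median scaling gave 6469 up and 2596 down. The cell cycle list (28 of 29 down, median −0.47 per mM, adjusted p = 6.88e-17; adjusted p = 0.0487 with an estimated correlation), p53 targets (15 of 16 up, 0.17 per mM, adjusted p = 4.16e-06) and inflammatory genes (17 of 21 down, −0.27 per mM, adjusted p = 2.76e-08) had one-sided slopes, the last with 18 down adjusted over the list alone and the others with the same numbers. PPAR alpha targets also passed (11 of 15 up, 0.17 per mM; adjusted p = 0.0144 with an estimated correlation). Of their mean change at 5 mM, cholesterol genes had 69.9% at 1 mM and 91.6% at 2 mM, hepatocyte markers 43.8% and 61.9%, PPAR alpha targets 27.5% and 48.8%, p53 targets 16.6% and 40.4%, and cell cycle genes 16.4% and 21.5%.

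**Figure D3:**
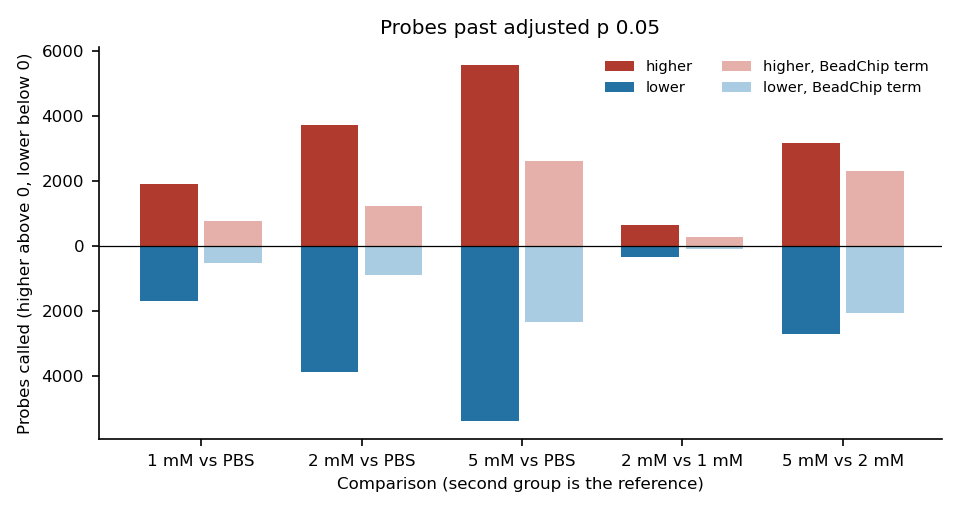
Bars give the number of probes higher and lower at adjusted p under 0.05 in each comparison, without and with BeadChip as a term. The bars are longest for 5 mM against PBS, with 5586 higher and 5400 lower, and shortest for 2 mM against 1 mM, with 639 and 345.

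Calls at different doses were compared to ask whether the same probes moved. Of the probes called at 2 mM, 6622 (87.0%) were called in the same direction at 5 mM (3361 higher and 3261 lower) and 42 in the opposite direction. Independent lists would share 1018 higher and 1018 lower. Simulated unchanged groups against the same PBS arrays shared 0.02 on average and 2 at most in 100 draws. These draws held no changed probes and so hardly any calls. They cannot show how much the shared PBS arrays add to the overlap of real calls. With the PBS arrays split between the comparisons the overlap was 4692.1 on average (4221 to 5094, 20 splits). All PBS arrays were on BeadChip 1, which held no 2 mM or 5 mM array. A shift of that BeadChip would enter both comparisons in the same direction, and splitting the PBS arrays cannot remove it. With BeadChip as a term, which links PBS to the other doses through 1 mM replicate 1 alone, 1940 probes were shared. The correlation of the fold changes was 0.838 (0.474 simulated, 0.780 with split PBS arrays), and their covariance lay 0.192 above the simulated 0.00806. For 1 mM and 2 mM, 3249 probes (89.8%) were shared in direction and 0 opposed, beside 350 higher and 320 lower for independent lists and 1712 with split PBS arrays (1246 to 2057). For 1 mM and 5 mM, 3124 (86.3%) were shared and 54 opposed, beside 523 and 446 for independent lists and 1783.95 with split arrays (1252 to 2278). The covariances were 0.0825 and 0.119, beside 0.00829 and 0.00835 simulated. Ttr, Gsta4, Fcgrt, Aldh1a1, Apoc4 and Apoe rose at every dose, and Mvk and Lss fell at every dose.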

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

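Chosen only after the result was seen were the tests of a BeadChip difference at 1 mM and of BeadChip and normalization for the fall of the cell cycle list. An array stood apart from its group, by the gap to its nearest neighbour over the range of the group, in 51 of 796 groups (6.41%), where chance flags about 1 in 20. Among list means it was 8 of 116 (6.90%), among named genes 41 of 648 (6.33%), and among array measures 2 of 32 (6.25%). Both of these were 2 mM replicate 5, low on component 4 (score −3.70, gap over range 0.748) and high on component 5 (score 27.4, gap over range 0.790). Not flagged by this rule, but far out on a component, were 1 mM replicate 4 (−29.2 on component 3) and 1 mM replicate 1 (−28.0 on component 4). Without these 3 arrays 2084 probes in place of 3619 were called at 1 mM against PBS, and 358 in place of 984 for 2 mM against 1 mM. The array that stood apart most often was 2 mM replicate 5 (8 times), followed by 1 mM replicate 4 and 5 mM replicate 1 (5 each).

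Among lists, a single array was the high one for PPAR alpha targets at 1 mM (replicate 4, gap over range 0.844), ketone body metabolism at 2 mM (replicate 1, 0.951), genes that deacetylase inhibitors induce in PBS (replicate 2, 0.742), the unfolded protein response at 2 mM (replicate 5, 0.735), inflammatory genes at 2 mM (replicate 5, 0.745) and mesenchymal markers at 5 mM (replicate 3, 0.847). It was the low one for oxidative phosphorylation at 1 mM (replicate 3, 0.892) and the unfolded protein response in PBS (replicate 4, 0.753).

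Among named genes in PBS, the gap over range was 0.773 for Fcgrt (replicate 4 low), 0.711 for Tcof1 (replicate 4 high), 0.769 for Acaa2 (replicate 3 low), 0.721 for Bdh1 and 0.732 for Idh1 (replicate 5 high), 0.794 for Hdac8 (replicate 1 high), 0.775 for Slc25a1 and 0.745 for Tek (replicate 2 high), 0.780 for Chordc1 (replicate 3 high) and 0.847 for Sox9 (replicate 2 low). At 1 mM it was 0.867 for Ttr and 0.894 for Slc25a20 (replicate 4 high), 0.844 for Etfb and 0.837 for Cd14 (replicate 4 low), 0.860 for S100a7a and 0.889 for Pcx (replicate 3 high), 0.843 for Tcof1 (replicate 2 high), 0.924 for Creld2 (replicate 1 low) and 0.879 for Fas (replicate 1 high).

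At 2 mM the values were 0.744 for Gsta4 and 0.772 for H2ac15 (replicate 5 low), 0.808 for Gstt1 and 0.792 for Cxcl2 (replicate 5 high), 0.788 for H2ac21 (replicate 3 high), 0.768 for Bdh2 (replicate 3 low), 0.901 for Bub1b and 0.753 for Lpin1 (replicate 2 high) and 0.730 for Ppargc1a (replicate 4 low). At 5 mM they were 0.853 for Flrt1, 0.869 for Cyp4a12a and 0.865 for Shmt2 (replicate 1 low), 0.835 for D17H6S56E-5 and 0.955 for Fas (replicate 1 high), 0.931 for Aldh1a7, 0.845 for Pcx, 0.861 for Ndufs8 and 0.887 for Creld2 (replicate 2 low), 0.862 for Acot1 and 0.905 for Myc (replicate 4 low), 0.871 for Mdh2 (replicate 4 high) and 0.862 for Hspd1 (replicate 3 high).

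The large number of changed probes was set against other groupings of the same arrays, with 100 of 126 groupings drawn for each comparison. In each of the 5 comparisons only 1 grouping, the real one, gave as many calls. The other groupings mixed arrays of the 2 groups. Where groups differ for any cause, such mixing widens the spread and lowers the calls. The ranking therefore cannot tell chance from other causes and does not exclude it. The real and the highest other numbers were 3619 and 1826 at 1 mM against PBS, 7615 and 7 at 2 mM against PBS, 10986 and 8120 at 5 mM against PBS, 984 and 149 for 2 mM against 1 mM and 5873 and 3414 for 5 mM against 2 mM. The high others moved 4 arrays and so nearly exchanged the 2 groups.

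The BeadChip is the technical difference that runs with dose. If BeadChip shifts had made the calls at 5 mM, the shift of a probe between BeadChips should have had the direction and size of its change, but over the 10986 called probes the median ratio of shift to change was 0.00172 (quartiles −0.295 and 0.287). At 1 mM, the array on BeadChip 1, which shares its BeadChip with PBS, was set beside the arrays on BeadChip 2, with the PBS arrays split so that the changes compared shared none. It showed a median of 0.7097 of their change on average (0.645 to 0.766 over 20 splits), where a PBS array in its place gave 0.000299 (−0.0807 to 0.111 over 30 splits). Both tests argue against a BeadChip difference as the main source of these changes. Both also rest on 1 mM replicate 1, which stood apart, and single probes, for which the fit with BeadChip as a term has a larger standard error, stay open.

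Of the mean fall of the cell cycle list at 5 mM, 21.5% was present at 2 mM. Within BeadChip 3, which held 2 mM and 5 mM arrays, its median change between these doses was −1.72, which a BeadChip difference could not give. With median scaling the list was at −2.34 relative to all genes, so quantile normalization was not the source either. Cell division and viability were not measured, and octanoate itself, its effect on the medium and toxicity at that dose were not told apart.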

How the results depend on the processing

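The alternative that left out 1 mM replicates 1 and 4 and 2 mM replicate 5 together was chosen only after the data were seen. Of 205 results for named genes 199 passed, and 162 passed under every alternative, while of 4447 values under alternatives 4355 stayed on their side of the threshold, 86 lost it, 6 gained it and 0 turned direction. Of 87 list results 34 passed, 26 of them always, with 19 values lost, 29 gained and 0 turned among 2027. The number of lists called stayed within 1.5 times of its value, at 8 to 14 for 1 mM (10), 10 to 14 for 2 mM (13) and 9 to 14 for 5 mM (11). Autophagy and acetyl-CoA supply at 5 mM were the lists most often gained. BeadChip as a fixed term ended 32 of the 205 gene results. Probes near background are limited by signal over background, and the cause of differences was not tested unless named.

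Counts of probes moved by over 1.5 times as follows. BeadChip as a fixed term gave 1295 at 1 mM, 2134 at 2 mM and 4965 at 5 mM against PBS, 373 for 2 mM against 1 mM, 4675 for the trend and 1940 shared between 2 mM and 5 mM, with median standard errors of 0.180, 0.224 and 0.266 against PBS in place of 0.114, 0.108 and 0.114. A minimum of 1.5-fold gave 663, 1936, 5226, 188 (2 mM against 1 mM), 1851 (5 mM against 2 mM), 5039 (trend) and 1767 (shared). With 1 probe per gene, where fewer probes were tested, the numbers were 2163, 4424, 6298, 3688 (5 mM against 2 mM), 5966 (trend) and 3895 (shared). An adjusted p under 0.01 gave 1763 at 1 mM against PBS and 343 for 2 mM against 1 mM. Quantile normalization without background correction gave 1570 for 2 mM against 1 mM, median scaling 432 there and 4266 shared, and only the groups compared 425. Only BeadChip 2 gave 27 for 2 mM against 1 mM and only BeadChip 3 gave 3765 for 5 mM against 2 mM, with fewer arrays. Only BeadChip 1, with the spread pooled from all groups, repeats the fixed term for 1 mM against PBS (1295) and is counted a second time among the alternatives. Without the 3 arrays together 2084 remained called at 1 mM against PBS and 358 for 2 mM against 1 mM.

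With each array left out in turn, the counts ran from 2756 to 3481 at 1 mM against PBS, from 6927 to 7304 at 2 mM, from 10236 to 10622 at 5 mM, from 650 to 807 for 2 mM against 1 mM, from 5085 to 5581 for 5 mM against 2 mM, from 9697 to 10502 for the trend and from 6064 to 6803 for the overlap of 2 mM and 5 mM. The 650 came without 1 mM replicate 2. Lists called ran from 10 to 11, from 11 to 13 and from 11 to 13 at the 3 doses.

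The replicate number as a block gave 3464, 7636, 10825, 749 and 5669 probes in the order of comparisons above, 10109 for the trend and 6550 shared, none moved by over 1.5 times. Same-numbered arrays of different groups showed little common deviation (mean correlation 0.011 over 25 pairs, from −0.041 to 0.054). Pairs with different numbers had a mean of −0.0028. Of 18 arrays 3 correlated best with their own number, so no clear pairing was seen, which does not exclude a common origin. With this block Eng (adjusted p = 0.0503) and Idh3g (0.05) at 5 mM no longer passed, Cftr (0.0311) and autophagy (0.0368) passed, and no other named gene or list changed its call.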

Other observations

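All gene families and turning genes in this part were chosen after values were seen, as was the test of shared 2 mM arrays, whereas the tests on PPAR alpha targets and on genes that deacetylase inhibitors induce were fixed in advance. The adjusted p-values of families therefore only describe these data. Families also repeat members of the fixed lists, such as Mcm2 to Mcm7 and Cenpa (cell cycle), Gsta4 and Gstp1 (NRF2), Aars and Nars (integrated stress response) and Apob and Apoe (hepatocyte markers). They are not separate findings for those genes. Of 22 measured glutathione S-transferases 20 rose and 0 fell at 5 mM against PBS (median 1.53, BeadChip value 1.40, camera's adjusted p = 0.00279 with an estimated correlation over 14 families), with Gstt3 at 2.21 ± 0.08 and Gstm7 at 2.10 ± 0.11. Cytochromes P450 had 14 of 23 higher and 2 lower (0.75, BeadChip value 0.69, adjusted p = 0.00847), with Cyp2d22 at 2.51 and Cyp27a1 at 2.49. They were picked by the form of their symbols, which left out Cyp51 (−1.55). Aldehyde dehydrogenases had 10 of 13 higher and 1 lower (0.71, BeadChip value 0.87, adjusted p = 0.00847), with Aldh3b1 at 1.43 and Aldh16a1 at −1.20. Glucuronosyltransferases of the Ugt family had 5 of 7 higher and 1 lower (1.59, BeadChip value 1.33, adjusted p = 0.0169), with Ugt1a10 at 1.79. Their median was already 1.54 at 2 mM and moved by 0.02 between 2 mM and 5 mM (adjusted p = 0.675). Ugt1a6a, Ugt1a6b and Ugt1a10 had much the same values at 2 mM (1.54, 1.58 and 1.77) and 5 mM (1.54, 1.59 and 1.79). Whether their probes read shared sequence was not examined, so they may not count as separate genes. Ugt2b34, not above background on any PBS array, did rise further (0.73 at 2 mM, 1.70 at 5 mM). Apolipoproteins had 7 of 12 higher and 1 lower (0.84, BeadChip value 0.63, adjusted p = 0.0155), with Apoc2 at 2.18. This set was also picked by symbol and took in the receptor Apobr (−0.17) and the mitochondrial Apool (0.18), neither of them called. Serpins (11 higher and 1 lower of 20, 0.36), kinesins (10 higher and 11 lower of 25, −0.12) and chemokines (5 higher and 8 lower of 16, −0.69) did not pass with an estimated correlation (adjusted p = 0.108, 0.108 and 0.0949), nor did keratins (−0.25) and S100 proteins (−0.10).

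All 7 measured minichromosome maintenance genes were lower at 5 mM (median −2.49, BeadChip value −2.41, adjusted p = 0.00614) and at 1 mM (−0.48). Centromere proteins had 14 of 16 lower and 0 higher (−1.88, BeadChip value −2.00, adjusted p = 0.00131), with Cenpa at −2.45. Aminoacyl-tRNA synthetases had 10 of 15 lower and 1 higher at 5 mM (−0.34, BeadChip value −0.26, adjusted p = 0.0259), and 11 lower and 0 higher already at 2 mM (−0.37). Vars fell by 1.68 at 5 mM. Histone genes split by class at 5 mM. Of 15 measured H2A genes 12 fell and 2 rose (median −1.57, BeadChip value −1.64, −1.54 with median scaling), 10 of them by at least 2-fold, and of 8 H3 genes 7 fell and 0 rose (−0.46, BeadChip value −0.67, −0.37 with median scaling). In contrast 8 of 11 H2B genes rose and 1 fell (0.73, BeadChip value 0.70, 0.78 with median scaling), and 7 of 11 H4 genes rose and 3 fell (0.49, BeadChip value 0.50, 0.69 with median scaling). Of 2 H1 genes 1 rose. All replication-dependent histones together did not pass (47 genes, median −0.33, adjusted p = 0.29). The classes were not uniform, since H2ac18 (1.32) and H2ac19 (1.235) rose among H2A genes. Probes of near-identical histone genes can share targets, and which forms of histone RNA they read was not examined. The values therefore need not give the total message of a class, and this split was not tested further.

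Some probes turned between doses, fewer than independent lists would give. Of probes called at 2 mM against PBS and at 5 mM against 2 mM, 134 were higher and then lower and 157 lower and then higher, 291 in all, beside 3053 called in the same direction. Independent lists would hold 493 and 597. Simulated unchanged groups that shared the 2 mM arrays held 0 in 100 draws, but without changed probes they could hardly hold any. Both comparisons use the 2 mM arrays, which may by chance alone make such probes, but with these arrays split between the comparisons 119.2 remained on average (110 to 129 over 20 splits), so shared arrays are not the source of all of them. Of the genes that turned, only Lcn2 and Hp did so by at least 2-fold both ways. Of single genes, Lcn2 (1.39 ± 0.10 at 2 mM over PBS, −3.70 ± 0.11 at 5 mM over 2 mM), Hp (1.18 and −1.82), Saa3 (0.84 and −3.90) and Orm1 (0.60 and −1.17) rose and then fell, as did Egr1 (1.43 and −0.61). With BeadChip as a term the rises of Saa3 (0.33, adjusted p = 0.40) and Orm1 (0.73, adjusted p = 0.077) did not pass, while those of Lcn2 (1.26) and Hp (0.84) did. Trib3, a target of the integrated stress response, fell and then rose (−0.78 and 1.18).

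PPAR alpha activation was set as a hypothesis. It needs its targets to rise together. Over the 15 measured targets the list's median at 5 mM was 0.897 (adjusted p = 0.00588 with an estimated correlation). Other targets of the list, among them Cpt1a, had no tested probe and are not covered. The values of the measured targets go with the hypothesis, although other regulators share these targets and the receptor itself was not manipulated. A response like that to deacetylase inhibitors, for which the link of lipids to histone acetylation gives a reason, may be present or not. The median of genes that such inhibitors induce was 0.445 at 5 mM (adjusted p = 0.316 with an estimated correlation), with 8 higher and 5 lower of 13, which neither excludes nor shows it. At 2 mM the same list did not pass camera in the main fit (adjusted p = 0.0834). Over the alternatives its adjusted p there ran from 0.0195, without the filter on dim probes, to 0.253. No acetylation was measured in the arrays.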
